A study of Mus musculus with 8 samples.

How the data were processed

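Total RNA from 8 cultures of mouse CD4 T cells was labelled with biotin and measured on Affymetrix arrays, 1 array per culture. Per the labels, naive cells (CD25-negative, CD62L-high and CD44-low) were sorted from spleen and lymph node of C57BL/6 mice that were wild-type or lacked Tet2. They were activated with antibodies to CD3 and CD28 and grown under Th1 conditions (10 ng/ml IL-12, 30 U/ml IL-2 and an antibody to IL-4) or Th17 conditions (0.5 ng/ml TGF-β1, 10 ng/ml IL-6 and antibodies to interferon-γ and IL-4). Whether IL-23 and IL-1β were added to these Th17 cultures is not given in the sources used here.

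The deposited values are 1 log2 value per probeset and array, which the authors made with RMA and Partek, per the submitters' processing notes. The log base is not given in the sources used here, and log2 was taken from the range of the values, with a lowest value of 2.71 and a highest value of 13.8 or more on each array. Software versions, filters and the genome build behind the probeset design are likewise not given. The table held 35556 probesets, of which 21789 had 1 gene symbol, 1621 had several and 12146 had none listed. Symbols were checked by Entrez ID against a gene table for the assembly GRCm38, which held 21698 of the single-symbol probesets and changed 0 symbols. For the 999 genes with more than 1 such probeset, the one with the highest mean over the 8 arrays was used, which left 19938 genes. No gene was left out for a low level, and no array was left out. Il22 had no probeset with a single symbol, so it was not analysed here.

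The 4 groups (Th1 or Th17, wild-type or Tet2-deficient) held 2 arrays each, named biological replicates. A linear model with a mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), which gave 4 residual degrees of freedom and 8.44 prior degrees of freedom. The contrasts were Tet2-deficient minus wild-type in Th1 cells and in Th17 cells, the difference of those 2 contrasts, their mean, and Th17 minus Th1 cells in each genotype. All tests were two-sided. P values were adjusted over the 19938 genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Errors given as SE come from this fit, with confidence intervals of 95%; SD is the spread of the 2 arrays of a group. The likeness of the genotype effects in Th1 and Th17 cells was described by correlations across genes, which are not independent replicates, so no p is given.

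The groups, the tests, the alternatives, 34 gene lists and the rule for naming genes were fixed before the data were examined. In each genotype comparison within a cell type the rule took Tet2, then the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between genotypes. Where fewer were called, the smallest unadjusted p in that direction filled the places. In the other comparisons it took 5 genes per direction. Predicted genes, clones and the genes of microRNAs, snoRNAs and snRNAs were counted but not named. A fixed panel of cytokines, lineage factors and Tet genes was added in every comparison, and up to 4 members with the smallest p for each gene list described. The lists covered T cell programs, signalling and metabolic pathways, markers of other cell types and sample checks. The 33 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of 1 contrast. The same test with an estimated correlation and limma's fry were run beside it. The PValue of fry tests whether the genes of a list move, on balance, one way, and its PValue.Mixed whether they change in either direction.

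The fit was tested on simulated data with the same 8-array layout. Of 50 genes given a log2 change of 0.5, 64% were recovered in the Th1 contrast and 42% in the Th17 contrast, and of 50 given a change of 1, 100% in each. False calls among genes given no change numbered 17 and 13, beside 32 and 21 genes recovered at 0.5 and 50 at each larger change. Changes of 0.5, 1, 1.5 and 2 were simulated together, 50 genes of each, which loosens the adjusted threshold. The noise was independent between genes and drawn from the moderated variances. These shares therefore do not carry over to the real data, where Il3 at -1.13 in Th1 cells was not called (adjusted p = 0.179). Of 10 lists shifted by 0.4 log2 units, camera recovered 10 at the preset and 10 at an estimated correlation, with 0 false calls in each. At a shift of 0.2 it recovered 10 (1 false call) and 0, and at 0.1 it recovered 4 and 0. These lists were random genes with independent noise, so they could not test the preset on correlated genes. The correlation estimated in the real lists ran from -0.0418 (NK markers) to 0.618 (cell cycle), with 0.115 for T cell cytokines and 0.230 for cholesterol genes. The simulation therefore does not show that the preset p values of such lists are right. Alternatives varied the normalization, the moderation, array weights, the choice of arrays and probesets, the threshold and the list test, and left out each array in turn; a fit that leaves 1 array in a group assumes that this array varies like the others. The number of arrays limits the precision: the median SE of a genotype difference within a cell type was 0.125 log2 units.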

Results

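Gene expression was measured on 8 arrays in 4 groups of 2: wild-type Th1, Tet2-deficient Th1, wild-type Th17 and Tet2-deficient Th17 cells. Tet2 is an enzyme that oxidises methylated cytosine in DNA, and the series asks how demethylation by Tet2 bears on the cytokines that T cells express. Array medians lay between 6.47 and 6.53 log2 units, with lowest values of 2.71 to 2.89 and highest values of 13.8 or more. Across genes, the arrays of 1 group correlated at 0.990 to 0.994 and arrays of different cell types at 0.977 to 0.981. For the median gene, a log2 difference of 0.27 between genotypes reached an unadjusted p of 0.05. The single probeset for Tet2 (10502284) read 8.08 ± 0.0789 log2 units (SD, n = 2) in wild-type and 8.05 ± 0.104 in Tet2-deficient Th1 cells, and 8.52 ± 0.0131 and 8.40 ± 0.0346 in the matching Th17 cells. Its position relative to the deleted part of the gene is not known here, so it does not check the genotype labels.

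The first comparison asks what the loss of Tet2 changed in Th1 cells. Ifng, which encodes interferon-γ, the signature cytokine of Th1 cells, fell 2.68-fold: its probeset (10366586) read 11.7 ± 0.228 log2 units (SD, n = 2) in wild-type and 10.3 ± 0.173 in Tet2-deficient Th1 cells. The log2 difference was -1.42 (SE 0.139, confidence interval -1.72 to -1.12, adjusted p = 0.00391), and both Tet2-deficient arrays lay below both wild-type arrays. No other gene passed the test. The lower genes with the next smallest p were Prdm1, which encodes the transcriptional repressor Blimp-1, at -0.77 (SE 0.115, adjusted p = 0.176), and the cytokine Il3 at -1.13 (SE 0.176, adjusted p = 0.179). The cytokine Il24 differed by -0.83, Themis, a factor in T cell receptor signalling, by -0.75, Sytl3 by -0.69, Fthl17f by -0.66 and Pcdhb21 by -0.53, with adjusted p between 0.191 and 0.607. In the other direction, Cypt2 differed by 0.67, Lce1c by 0.67, Olfr715 by 0.64, Wars, the tryptophanyl-tRNA synthetase, by 0.61, Ripor2 by 0.56, Pxdc1 by 0.54, Olfr1339 by 0.54 and the lysosomal protease Lgmn by 0.50, with adjusted p between 0.246 and 0.760. Some of these read near the level of Xist on the Th1 arrays (4.83 to 5.11), so their differences are at best lower bounds in size. These were Cypt2 (5.23), Olfr715 (5.31) and Pxdc1 (5.19) in wild-type cells and Fthl17f (5.35) and Sytl3 (5.42) in Tet2-deficient cells. Pcdhb21 read 5.21 and 4.68, so its expression is not shown. In the fixed panel, Il21 differed by -0.56 (SE 0.172, adjusted p = 0.824) and Tbx21, the lineage factor of Th1 cells, by 0.20 (SE 0.159, adjusted p = 0.912). The values were 0.03 for Il17a, 0.00 for Il17f, -0.05 for Il10, 0.07 for Il2, 0.05 for Il4, -0.29 for Csf2, -0.12 for Tnf, 0.14 for Foxp3, 0.19 for Tet1 and 0.16 for Tet3. Il10 read 4.09 and 4.04, under that level of Xist, so its expression is not shown. Il17a (6.04 and 6.07), Il4 (6.11 and 6.17) and Tet1 (5.94 and 6.13) lay under the array medians (6.47 to 6.53). A fall of these 3 genes could hardly have been seen. The array holds 2 other Tet1 probesets, 1 of them with the opposite sign.

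Limma called 1 of 19938 genes, and 1145 had an unadjusted p under 0.05 (552 higher, 593 lower) where 996.9 would be expected by chance. Ifng stayed past the threshold in 15 of 21 alternatives (adjusted p 0.00129 to 0.921). It did not pass without Th1 wild-type replicate 2 (-1.26, adjusted p = 0.0685), without Th1 Tet2-deficient replicate 2 (-1.30, adjusted p = 0.129). Nor did it pass without Th17 wild-type replicate 1 and Th17 Tet2-deficient replicate 2 together (adjusted p = 0.0838), with no moderation of the variance (adjusted p = 0.921), with the Th1 arrays fitted alone (0.161) or with all probesets tested (0.353). Without Th1 Tet2-deficient replicate 1, 2 genes were called, Ifng and Il3 (-1.42, adjusted p = 0.0336, against 0.0336 to 0.921 over 20 alternatives).

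**Figure D1:**
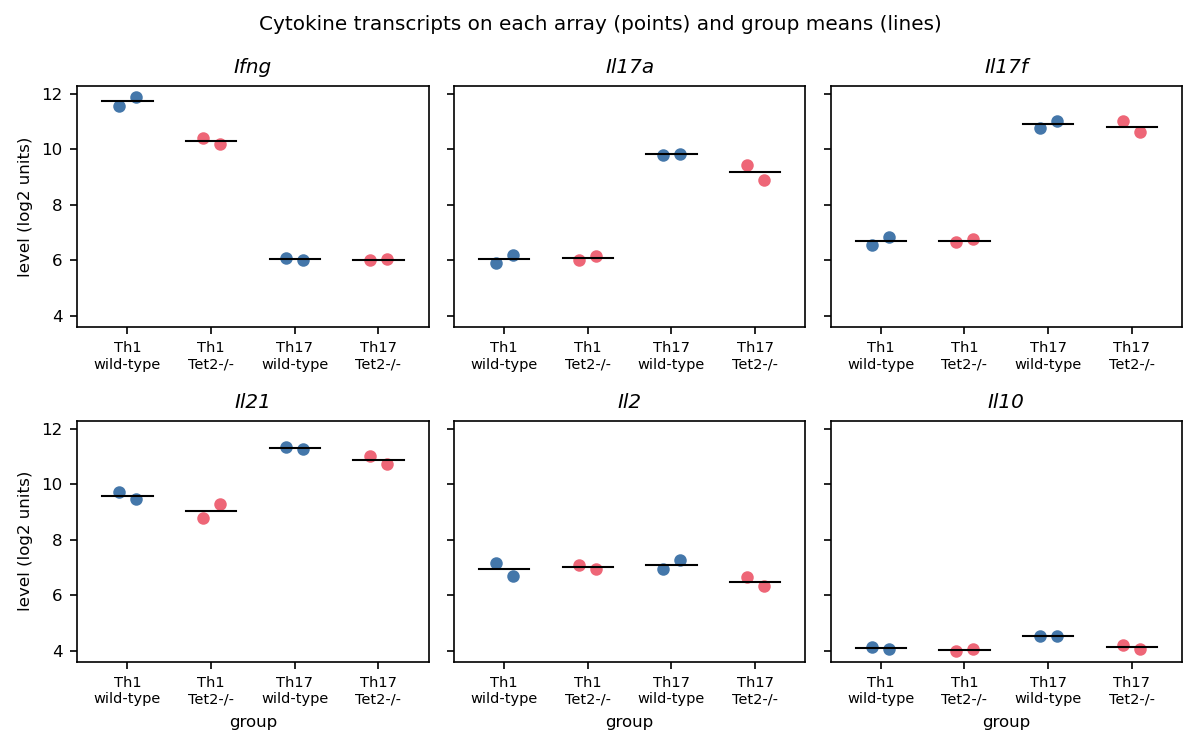
Levels of 6 cytokine transcripts (log2 units) in the 4 groups, with 1 point per array and a line at the mean of the 2 arrays of a group. Ifng reads 11.7 in wild-type and 10.3 in Tet2-deficient Th1 cells, and 6.04 and 6.03 in the matching Th17 cells.

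Among the gene lists, cell cycle genes fell in Tet2-deficient Th1 cells: 26 of 27 measured members were lower, with a median log2 difference of -0.28 (camera adjusted p = 1.66e-09; adjusted p = 0.660 with an estimated correlation). Tyms differed by -0.48, Mki67 by -0.50, Bub1 by -0.55 and Bub1b by -0.46, and 0 members passed the test over all genes or adjusted over the list alone. Camera called 6 further lists, each with an adjusted p = 0.660 with an estimated correlation. Genes of T cell receptor activation rose (19 of 22 higher, median 0.14, adjusted p = 0.0199, with Fosl1 at 0.38 and Egr3 at 0.21), as did genes of the amino acid and ER stress response (17 of 22 higher, median 0.13, adjusted p = 0.0318, with Chac1 at 0.51 and Phgdh at 0.38). TGF-β response genes rose (16 of 18 higher, median 0.14, adjusted p = 0.0318, with Smad3 at 0.40), as did interferon-γ response genes (12 of 17 higher, median 0.18, adjusted p = 0.0413, with Irgm1 at 0.44 and Irf1 at 0.57 but Cxcl10 at -0.31). Genes of the stress and dissociation list, such as heat shock proteins, fell (0 of 10 higher, median -0.13, adjusted p = 0.0447, with Hsph1 at -0.29). In these 5 lists 0 members passed the test over all genes or adjusted over the list alone. Markers of stromal and endothelial cells rose (9 of 11 higher, median 0.08, adjusted p = 0.0447), with 0 members called over all genes and 2 adjusted over the list alone, Sparc at 0.51 and Pecam1 at 0.44. T cell cytokines were not called as a list (adjusted p = 0.0849; median 0.01, mean -0.13), with 1 member called over all genes and 4 adjusted over the list alone, Ifng, Il3, Il24 and Il21. Lists for CD8 T, B, NK, myeloid and erythroid cells did not pass, the smallest adjusted p being 0.0803 for B cells.

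The cell cycle call held in 13 of 13 alternatives that kept the preset correlation (adjusted p 8.90e-13 to 0.00125). Without Th1 wild-type replicate 1 the adjusted p was 0.134 for T cell receptor activation, 0.250 for amino acid and ER stress, 0.269 for TGF-β and 0.104 for stromal markers. Without Th1 wild-type replicate 2 it was 0.591 for interferon-γ response, 0.591 for stress and 0.202 for stromal markers. Without Th1 Tet2-deficient replicate 1 it was 0.384 for TGF-β. Without Th1 Tet2-deficient replicate 2 it was 0.0524, 0.684, 0.181, 0.181 and 0.355 for T cell receptor activation, amino acid and ER stress, interferon-γ response, stromal markers and stress. The stress call also ended without any one of the 4 Th17 arrays (0.0556 to 0.0612), and the stromal call without either Tet2-deficient Th17 array (0.0598 and 0.0599). With the Y-linked level as a covariate both had 0.0618, and without Th17 wild-type replicate 1 and Th17 Tet2-deficient replicate 2 together stress had 0.0670 and stromal markers 0.0558. With dim genes left out the TGF-β call ended (0.0510).

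The second comparison asks the same of Th17 cells. No gene passed the test there. The genes with the smallest p were Lum, an extracellular matrix proteoglycan, 2.03-fold higher in Tet2-deficient cells (log2 1.02, SE 0.133, adjusted p = 0.0689; 7.04 ± 0.0857 log2 units in wild-type and 8.07 ± 0.0937 in Tet2-deficient cells, SD, n = 2), and Gpr83, a receptor found on regulatory T cells, 1.93-fold lower (-0.95, SE 0.128, adjusted p = 0.0689). Lta, which encodes lymphotoxin-α, differed by -0.95 (SE 0.155, adjusted p = 0.177) and Ccl20, the ligand of the Th17 chemokine receptor Ccr6, by -1.01 (SE 0.176, adjusted p = 0.224). Il17a, the signature cytokine of Th17 cells, read 9.83 ± 0.0295 in wild-type and 9.17 ± 0.364 in Tet2-deficient cells (-0.66, SE 0.164, adjusted p = 0.730), while Il17f differed by -0.08 (SE 0.161). Further panel members read -0.40 for Il10, -0.60 for Il2, -0.42 for Il21, -0.45 for Tnf, -0.54 for Tbx21, -0.20 for Csf2, -0.02 for Il4, -0.01 for Ifng, -0.01 for Foxp3, -0.13 for Tet2, -0.04 for Tet1 and 0.04 for Tet3. Il4 (5.95 and 5.93) and Ifng (6.04 and 6.03) lay under the array medians (6.47 to 6.53), so a fall of either could hardly have been seen. The other named genes with higher levels were Klrd1, an NK cell receptor subunit, at 1.24, Ly6g at 0.99, Lgr4 at 0.76, Dgat1, an enzyme of triglyceride synthesis, at 0.75, Bcl6, the lineage factor of follicular helper cells, at 0.75, Atp6v0d2 at 0.63 and Usp18, an interferon-induced protease, at 0.54. Those with lower levels were Emp1 at -0.88, Rny3 at -0.86, Rbl2, a cell cycle repressor of the retinoblastoma family, at -0.75, Pgf at -0.53 and Atrnl1 at -0.48. Adjusted p for these 12 genes ran from 0.177 to 0.649. Pgf read only 5.40 in wild-type and 4.87 in Tet2-deficient cells, near the level of Xist on the Th1 arrays, so its expression is not shown.

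Limma called 0 of 19938 genes, and 848 had an unadjusted p under 0.05 (561 higher, 287 lower) where 996.9 would be expected by chance. Of all genes, 37 had an unadjusted p under 0.01 and a change of at least 1.5-fold. Without Th17 Tet2-deficient replicate 1, 9 genes were called (3 higher, 6 lower), among them Klrd1 (1.65, adjusted p = 0.00195) and Ccl20 (-1.27, adjusted p = 0.0475). Without Th17 wild-type replicate 1, 2 were called. Array weights came out equal for the 2 arrays of each group, so they weighted groups and not single arrays. With them, Lum (adjusted p = 0.0304) and Gpr83 (0.0307) passed. Each of these 4 genes passed in 1 alternative, and in others the adjusted p reached 0.999 for Lum and Gpr83 and 1.00 for Klrd1 and Ccl20.

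The Th17 arrays also differ in sex-linked transcripts. Xist, which is expressed from the inactive X chromosome of female cells, read 5.20 and 10.1 log2 units in wild-type replicates 1 and 2 and 8.62 and 11.3 in Tet2-deficient replicates 1 and 2, against 4.83 to 5.11 in the 4 Th1 arrays. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty read 8.80, 7.82, 8.71 and 4.85 in the same Th17 arrays, against 7.94 to 8.24 in the Th1 arrays.

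**Figure D2:**
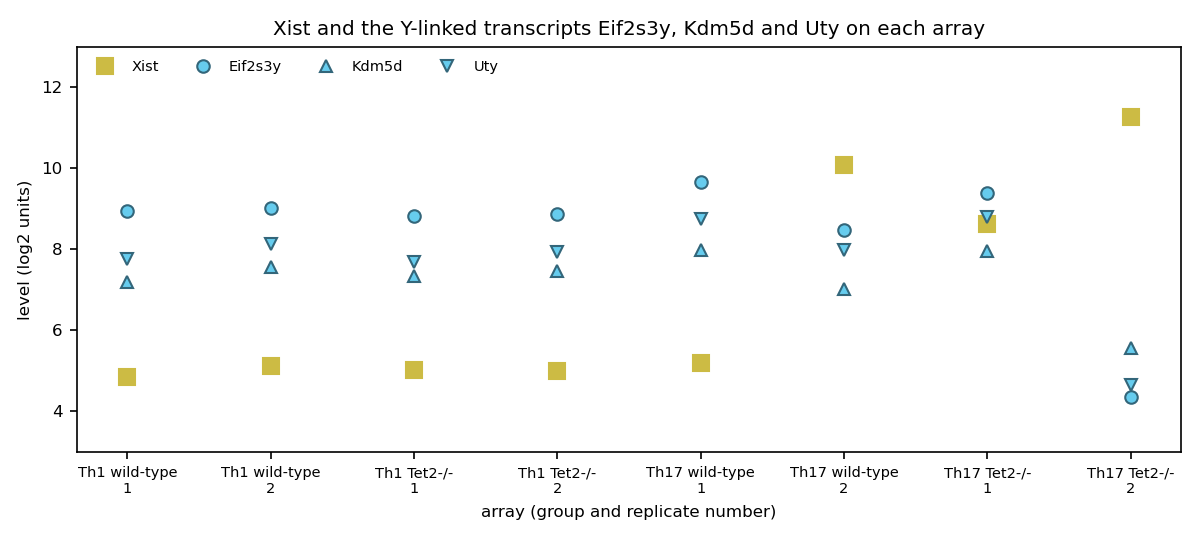
Levels (log2 units) of Xist (squares) and of 3 Y-linked transcripts (other symbols) on each of the 8 arrays. Xist lies between 4.83 and 5.20 on the 4 Th1 arrays and Th17 wild-type replicate 1, and between 8.62 and 11.3 on the other 3 Th17 arrays.

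In Tet2-deficient Th17 cells T cell cytokines fell as a group and genes of cholesterol synthesis rose. Of 26 measured cytokines 23 were lower, with a median log2 difference of -0.13 (camera adjusted p = 8.87e-09; adjusted p = 0.378 with an estimated correlation); 0 were called over all genes and 5 adjusted over the list alone, among them Lta, Il17a and Il2. Il10, also among them, read only 4.53 in wild-type and 4.13 in Tet2-deficient cells, under the level of Xist on the Th1 arrays (4.83 to 5.11), so its expression is not shown. All 18 measured cholesterol genes were higher, with a median of 0.24 (adjusted p = 1.03e-07; adjusted p = 0.517 with an estimated correlation), such as Hmgcs1, the first committed enzyme of the pathway, at 0.38 and Fdps at 0.36, with 0 called over all genes or adjusted over the list alone. Both calls held in 13 of 13 alternatives that kept the preset correlation, among them those that allowed for the sex-linked transcripts. Type I interferon response genes rose (17 of 21 higher, median 0.15, adjusted p = 0.00145; 0.623 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone, Usp18 and Mx1 (0.39). Cell cycle genes rose (23 of 27 higher, median 0.15, adjusted p = 0.00725; 0.728 with an estimated correlation; Bub1 at 0.45, Kif20a at 0.38), with 0 called over all genes or adjusted over the list alone. Th2 genes fell (9 of 11 lower, median -0.10, adjusted p = 0.00162; 0.525 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone, the chemokine receptors Ccr8 (-0.41) and Ccr4 (-0.53). Regulatory T cell genes fell (14 of 19 lower, median -0.07, adjusted p = 0.00846; 0.623 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone, Gpr83. Amino acid and ER stress genes fell (18 of 22 lower, median -0.09, adjusted p = 0.0101; 0.623 with an estimated correlation), as did T cell receptor activation genes (15 of 22 lower, median -0.08, adjusted p = 0.0498; 0.728 with an estimated correlation); 0 members of either were called over all genes or adjusted over the list alone. Stromal and endothelial markers rose (9 of 11 higher, median 0.15, adjusted p = 0.00365; 0.378 with an estimated correlation), with 0 called over all genes and 2 adjusted over the list alone, Lum and the proteoglycan Dcn (0.59). The lists for CD8 T, B, NK, myeloid and erythroid cells did not pass, the smallest adjusted p being 0.202 for NK cells.

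Without Th17 Tet2-deficient replicate 2 the cell cycle list turned downward (adjusted p = 0.0276) and the T cell receptor list upward (0.866). The adjusted p was then 0.543 for amino acid and ER stress, 0.0941 for regulatory T cell and 0.0802 for stromal genes. The cell cycle list also turned with the Y-linked level as a covariate (0.432) and without the arrays with the highest and lowest Y-linked level (0.0179). Without those arrays the adjusted p was also 0.182 for stromal, 0.323 for type I interferon, 0.432 for amino acid and ER stress and 0.323 for T cell receptor genes. With the covariate it was 0.295 for amino acid and ER stress and 0.721 for T cell receptor genes, and with dim genes left out 0.20 for stromal and 0.0570 for T cell receptor genes. Without Th17 wild-type replicate 2 it was 0.149 for amino acid and ER stress, 0.414 for regulatory T cell genes and 0.960, with the direction turned, for T cell receptor activation. Further calls ended without Th17 wild-type replicate 1 (0.0828 for cell cycle, 0.0871 for type I interferon), without Th17 Tet2-deficient replicate 1 (0.0717 for Th2 genes), and without either wild-type Th1 array (0.0520 and 0.0522 for T cell receptor activation).

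**Figure D3:**
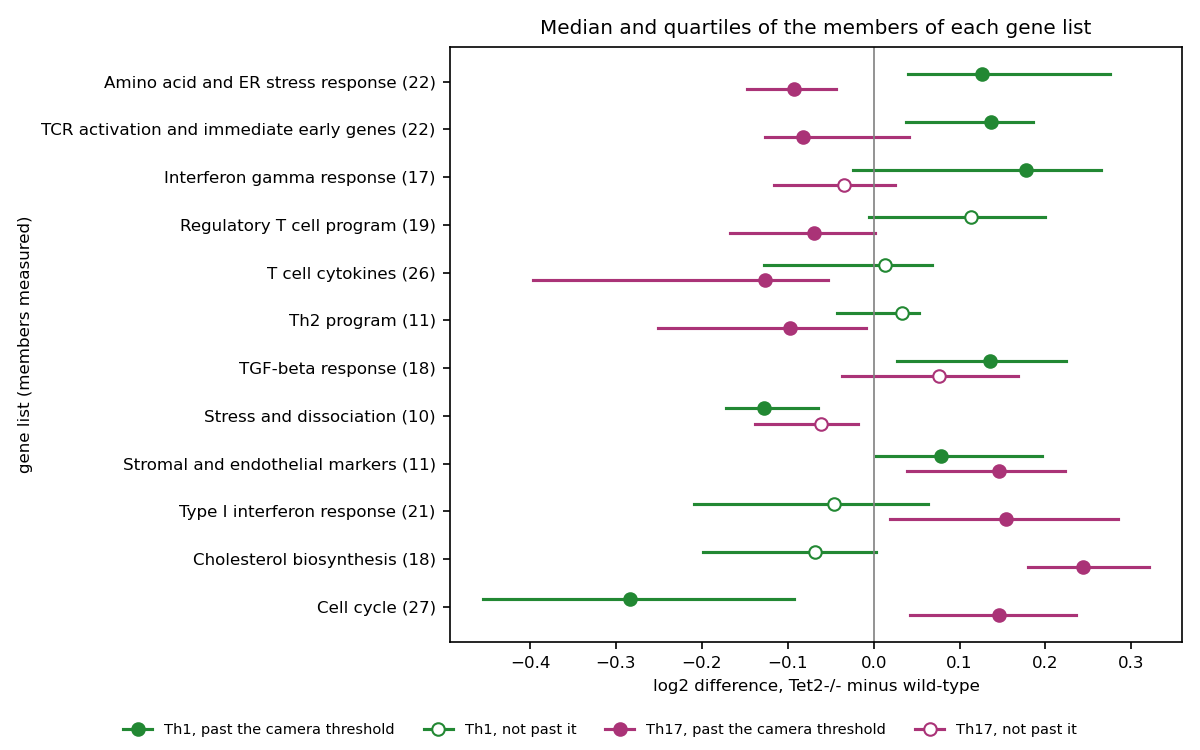
Median log2 difference, Tet2-deficient minus wild-type (points), and quartiles (lines) of the measured members of the 12 gene lists that camera called in Th1 or Th17 cells at the preset correlation; filled points are called, and the number of members stands beside each name. The cell cycle median is -0.28 in Th1 and 0.15 in Th17 cells, and the cholesterol median is -0.07 and 0.24.

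The third comparison asks whether Tet2 loss acted differently in Th17 and Th1 cells. The gene with the smallest p was Ifng, whose fall in Th1 cells stood beside a level of 6.03 to 6.04 in Th17 cells of either genotype (difference 1.41, SE 0.196, adjusted p = 0.150). Usp18 differed by 1.03, with -0.49 in Th1 and 0.54 in Th17 cells, and Prdm1 by 1.01 (adjusted p = 0.194 for both). Lum differed by 1.08, Atp6v0d2 by 0.91, Ccl20 by -1.23, Mapkapk3 by -1.12, Gucy1b1 by -0.79, Pgf by -0.77 and the calcium sensor Ncs1 by -0.77, with adjusted p of 0.306 to 0.758. Lum read 5.26 and 5.20 in Th1 cells, Gucy1b1 5.30 in wild-type Th1 cells and Pgf 4.87 to 5.40 in all groups, near the level of Xist on the Th1 arrays, so the differences given for these 3 genes do not measure a difference in effect. Ifng in Th17 cells lay under the array medians (6.47 to 6.53), as did Prdm1 (5.86 and 6.10), so a fall there could hardly have been seen. The differences for Ifng and Prdm1 therefore do not show that Tet2 loss acted differently on them. Limma called 0 genes, with 908 at an unadjusted p under 0.05 (584 higher, 324 lower) where 996.9 would be expected by chance, and 4 genes were called without Th17 Tet2-deficient replicate 1.

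Camera called 10 of 33 lists for this difference, none with an estimated correlation (adjusted p = 0.650 for T cell cytokines and 0.565 for the other 9). The cell cycle list shifted upward in Th17 relative to Th1 cells in 26 of 27 members (median 0.54, adjusted p = 9.34e-11; Bub1 at 0.99, Cenpf at 0.64), with 0 called over all genes and 2 adjusted over the list alone. Cholesterol genes did so in 17 of 18 members (median 0.33, adjusted p = 1.11e-06; Hmgcs1 at 0.72, Cyp51 at 0.51), with 0 called either way. Regulatory T cell genes shifted downward in 17 of 19 members (median -0.15, adjusted p = 0.000284; Gpr83 at -0.72, Izumo1r at -0.50), with 0 called over all genes and 1 adjusted over the list alone. These 3 calls held in 13 of 13 alternatives that kept the preset correlation. T cell receptor activation (20 of 22 lower), amino acid and ER stress (18 of 22 lower), interferon-γ response (12 of 17 lower), Th2 (10 of 11 lower) and T cell cytokine genes (18 of 26 lower) also shifted downward, and type I interferon (16 of 21 higher) and cytotoxic granule genes (13 of 16 higher) upward. Among these 7, members called over all genes numbered 0. Adjusted over the list alone, 4 type I interferon genes and 1 cytotoxic granule gene were called, all higher. Of the 3 cytokine genes called in that way, 2 were higher, against the direction of their list, and 1 was lower. Among the cytokines Ifng shifted upward, but its low level in Th17 cells (6.04 and 6.03) means that this does not show a different effect.

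Each of those 7 calls ended in some fits. Without Th17 wild-type replicate 2 (5 lists called in all) the adjusted p was 0.143 for T cell receptor, 0.372 for interferon-γ, 0.0702 for Th2, 0.521 for cytokine and 0.140 for cytotoxic genes. Without Th17 Tet2-deficient replicate 2 it was 0.153 for T cell receptor and 0.491 for both cytokine and cytotoxic genes. Without Th17 wild-type replicate 1 it was 0.0679 for cytotoxic genes, and without Th17 Tet2-deficient replicate 1 it was 0.162 for Th2 genes. Without Th1 Tet2-deficient replicate 2 it was 0.0725 for amino acid and ER stress and for type I interferon. Without Th1 wild-type replicate 1 it was 0.258 for type I interferon, 0.174 for Th2 and 0.157 for cytokine genes. Without Th1 wild-type replicate 2 it was 0.297 for interferon-γ and cytotoxic and 0.111 for cytokine genes. Without Th1 Tet2-deficient replicate 1 it was 0.255 for Th2 and cytokine and 0.213 for cytotoxic genes. With the Y-linked level as a covariate it was 0.230 for cytokine and 0.240 for cytotoxic genes. Without Th17 wild-type replicate 1 and Th17 Tet2-deficient replicate 2 together it was 0.108 for cytokine, 0.511 for cytotoxic and 0.0925 for type I interferon genes. With dim genes left out it was 0.169 for cytotoxic genes.

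The fourth comparison averages the effect of Tet2 loss over both cell types, with 4 arrays per genotype. Several cytokines were lower, though none passed: Ifng at -0.72 (SE 0.098, adjusted p = 0.124), Lta at -0.64, Il24 at -0.63 and, from the panel, Il21 at -0.49 (SE 0.122, adjusted p = 0.676). Gpr83 differed by -0.59, Fthl17f by -0.48 and Atrnl1 by -0.43, and in the other direction Lgr4, a receptor for R-spondins, by 0.59, Tnfrsf14, the herpesvirus entry mediator, by 0.56, Rasa3 by 0.55, Ripor2 by 0.53 and Igf1r by 0.43; adjusted p for these and for Lta and Il24 ran from 0.124 to 0.485. T cell cytokines fell as a list (16 of 26 lower, median -0.09, mean -0.17, adjusted p = 1.68e-07; adjusted p = 0.483 with an estimated correlation), with 0 called over all genes and 6 adjusted over the list alone, among them Ifng, Il24, Lta and Il3 (-0.61). Stromal and endothelial markers rose (10 of 11 higher, median 0.15, adjusted p = 0.000229; 0.342 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone, Lum (0.48), Pecam1 (0.34) and Sparc (0.35). Those calls held in 13 of 13 alternatives that kept the preset correlation. Cell cycle genes (21 of 27 lower, median -0.08) and stress and dissociation genes (9 of 10 lower, median -0.10) fell as well (adjusted p = 0.0330 for both; 0.792 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Il3 in Th17 cells (4.87 and 4.77) and Lum in Th1 cells (5.26 and 5.20) read near or under the level of Xist on the Th1 arrays (4.83 to 5.11). Ifng was low in Th17 cells too (6.04 and 6.03). The mean differences of these genes thus come almost wholly from the other cell type. Fthl17f read 5.35 in Tet2-deficient Th1 cells, also near that level, so its difference is at best a lower bound.

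Limma called 0 genes, with 1060 at an unadjusted p under 0.05 (671 higher, 389 lower) where 996.9 would be expected by chance. In turn, 5 were called without Th17 Tet2-deficient replicate 1, among them Il24 (-0.74, adjusted p = 0.0469, against up to 0.966 over 20 alternatives), and 2 with dim genes left out, among them Lgr4 (adjusted p = 0.0474, against up to 0.966). The cell cycle list turned upward without Th17 Tet2-deficient replicate 1 (adjusted p = 0.414). It did not pass without Th17 wild-type replicate 2 (0.118), Th1 Tet2-deficient replicate 1 (0.351) or Th1 wild-type replicate 2 (0.445). The stress list did not pass without Th17 Tet2-deficient replicate 1 (0.119), Th17 wild-type replicate 2 (0.118), Th1 Tet2-deficient replicate 2 (0.112) or Th1 wild-type replicate 2 (0.310). In all, 2 lists remained without Th17 Tet2-deficient replicate 1 and without Th1 wild-type replicate 2, and 8 were called without Th17 Tet2-deficient replicate 2.

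Across the 19938 genes, the effects of Tet2 loss in Th1 and in Th17 cells, which share no arrays, correlated at r = 0.0574 (Spearman's rho 0.0525), and 52.2% of genes had the same sign. Of 121 genes higher at an unadjusted p under 0.01 in Th1 cells and 128 in Th17 cells, 6 were shared against 0.777 for independent lists; of 105 and 74 lower genes, 2 were shared against 0.390. The correlation was -0.0390 without Th17 wild-type replicate 1, -0.00541 without Th17 Tet2-deficient replicate 1, 0.0127 without Th1 wild-type replicate 2, 0.0310 without Th1 Tet2-deficient replicate 2, 0.106 without Th17 Tet2-deficient replicate 2 and 0.124 without Th17 wild-type replicate 2.

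The fifth comparison sets wild-type Th17 against Th1 cells. Ifng was 51.4-fold lower in Th17 cells (log2 -5.68, SE 0.139, adjusted p = 2.35e-10; 6.04 ± 0.0411 against 11.7 ± 0.228 log2 units, SD, n = 2), the serine protease Gzmb 28.7-fold (-4.84), the cytotoxic granule protein Nkg7 23.2-fold (-4.53), the interferon-induced GTPase Iigp1 11.5-fold (-3.53) and the granzyme inhibitor Serpinb9 10.3-fold lower (-3.36). Il23r, the receptor that sustains Th17 cells, was 22.9-fold higher (4.52, SE 0.153), Il17f 18.3-fold (4.19), Il17a 13.8-fold (3.78), the transcription factor Maf 12.6-fold (3.65) and Atp6v0d2 8.74-fold higher (3.13). Il23r read 5.37 log2 units in Th1 cells, and Iigp1 and Serpinb9 5.37 and 5.35 in Th17 cells, near the level of Xist on the Th1 arrays (4.83 to 5.11), so folds of these 3 genes are at best lower bounds in either genotype. Ifng in Th17 cells (6.04) and Il17a in Th1 cells (6.04) lay under the array medians (6.47 to 6.53), so their folds may be lower bounds as well. Tbx21 fell (-2.56), Il21 rose (1.70), and Tet1 (0.51, adjusted p = 0.0148), Tet2 (0.44, adjusted p = 0.0366) and Il10 (0.44, adjusted p = 0.0253) read higher in Th17 cells. Il10 read 4.09 in Th1 and 4.53 in Th17 cells, under that level of Xist in both, so its expression is not shown. The other Tet1 probesets gave 0.78 (SE 0.127) and 0.048 (SE 0.134). The Th1 program was lower in 18 of 20 members (13 called over all genes, 15 adjusted over the list alone, camera adjusted p = 4.53e-20; 0.0610 with an estimated correlation) and the Th17 program higher in 17 of 19 (12 called higher and 1 lower over all genes, 14 and 1 adjusted over the list alone, adjusted p = 1.35e-14; 0.133 with an estimated correlation). Camera called 12 further lists. Lower in Th17 cells were genes of the interferon-γ response (10 members called lower over all genes, 12 adjusted over the list alone, with 0 and 1 higher), cytotoxic granules (6 and 9), the type I interferon response (6 and 9), chemokines (4 and 6, with 1 and 1 higher), myeloid markers (1 and 3), NK markers (1 and 2) and the cell cycle (0 and 0). Higher were those of the naive and memory program (7 members called higher over all genes, 9 adjusted over the list alone, with 3 and 3 lower), homing (5 and 7, with 1 and 1 lower), TGF-β response (4 and 4), cytokine receptors (7 and 11, with 3 and 4 lower), and glycolysis and hypoxia (5 and 7, with 1 and 2 lower). With an estimated correlation the adjusted p for these 12 lists ran from 0.0610 to 0.700.

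Limma called 1689 of 19938 genes, 1056 higher and 633 lower in Th17 cells. The count was 667 without Th17 wild-type replicate 2, 1013 without Th1 wild-type replicate 1, 808 without Th17 wild-type replicate 1 and Th17 Tet2-deficient replicate 2 together, and 87 with no moderation. The cell cycle call ended without Th1 wild-type replicate 2 (adjusted p = 0.110), and with dim genes left out those for TGF-β response (0.145), the naive and memory program (0.204), homing (0.267), cytokine receptors (0.334) and glycolysis and hypoxia (0.334) ended.

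In Tet2-deficient cells the same comparison gave 2078 genes, 1423 higher and 655 lower in Th17 cells. Il23r was 18.0-fold higher (log2 4.17, SE 0.153), Il17f 17.2-fold (4.10), Atp6v0d2 16.4-fold (4.04) and Maf 11.5-fold (3.52), and Nkg7 was 29.3-fold lower, Gzmb 25.4-fold, Ifng 19.4-fold (-4.28, SE 0.139), Iigp1 15.6-fold and Tbx21 9.85-fold lower. Ifng (6.03) and Nkg7 (6.21) in Th17 cells and Atp6v0d2 (6.36) in Th1 cells lay under the array medians (6.47 to 6.53). Their folds may be lower bounds. Of the genes higher in Th17 cells, 732 were called in both genotypes against 75.4 for independent lists, and of the genes lower, 322 against 20.8. Here too both contrasts share the variance of each gene, so some of the excess would arise from that alone. The Th1 arrays read as male (Xist 4.83 to 5.11, Y-linked mean 7.94 to 8.24). Th17 wild-type replicate 2 and both Tet2-deficient Th17 arrays carried Xist (10.1, 8.62 and 11.3). Sex composition thus differed between the cell types in either genotype and was not separated from cell type in these counts. Xist itself differed by 4.94 (SE 1.12, adjusted p = 0.0143), which follows the sex of the cells and does not measure an effect of cell type. Xist read 5.00 in Th1 cells, so the difference is at best a lower bound, and it varied among the Th17 arrays. It passed in 15 of 21 alternatives, and not with robust moderation (adjusted p = 0.226), none (0.289) or all probesets (0.137), nor without Th17 Tet2-deficient replicate 2 (3.62, adjusted p = 0.126), Th1 Tet2-deficient replicate 1 (0.0810) or Th1 Tet2-deficient replicate 2 (0.0689). The count was 815 without Th17 Tet2-deficient replicate 1, 1146 without Th17 Tet2-deficient replicate 2, 1003 without Th1 Tet2-deficient replicate 1, 1251 without Th1 Tet2-deficient replicate 2, 975 without the Th17 arrays with the highest and lowest Y-linked level and 166 with no moderation.

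The set tests differed in their calls. With an estimated correlation camera called 0 lists in each of the 5 contrasts tested. Fry called 0 lists as moving one way in the Th1, Th17, difference and mean contrasts and 18 between wild-type cell types, and its mixed test called 5, 5, 6, 7 and 26; neither compares a list with other genes. A further 13767 probesets with no or several symbols held 0 calls in each of the 4 genotype contrasts (645, 536, 535 and 640 at an unadjusted p under 0.05 for Th1, Th17, difference and mean) and 3 and 6 between cell types in wild-type and Tet2-deficient cells.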

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

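The comparison of cell cycle shifts with the gaps between replicates and the test of 1 array for their opposite direction were chosen after the values were seen. A test of the difference itself singled out 10 gene lists whose shift with Tet2 loss differed between Th17 and Th1 cells at the preset correlation. None passed with an estimated correlation (adjusted p = 0.565 for 9 lists, 0.650 for T cell cytokines). The shift in Th17 relative to Th1 cells was upward for cell cycle genes (adjusted p = 9.34e-11, 26 of 27 members, Bub1 at 0.99). It was upward for cholesterol synthesis (adjusted p = 1.11e-06, 17 of 18 members, Hmgcs1 at 0.72). For regulatory T cell genes it was downward (adjusted p = 0.000284, 17 of 19 members, Nrp1 at -0.88). T cell receptor activation genes shifted downward (adjusted p = 0.000284, 20 of 22 members, Fosl1 at -0.47). Amino acid and ER stress genes shifted downward too (adjusted p = 0.000284, 18 of 22 members, Phgdh at -0.72). Type I interferon response genes shifted upward (adjusted p = 0.000724, 16 of 21 members, Oas3 at 0.67). Interferon-γ response genes shifted downward (adjusted p = 0.0109, 12 of 17 members, Irf1 at -0.69). Th2 genes shifted downward (adjusted p = 0.0253, 10 of 11 members, Ccr8 at -0.45). Cytotoxic granule genes shifted upward (adjusted p = 0.0467, 13 of 16 members, Serpinb6b at 0.68). T cell cytokines shifted downward (adjusted p = 0.0475, 18 of 26 members, Lif at -0.66), with Ifng at 1.41 in the other direction. Ifng read only 6.04 and 6.03 in Th17 cells, so its value does not show that Tet2 loss acted differently on it. Il3, also in this list, was low there too (4.87 and 4.77).

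The cell cycle genes moved in opposite directions, with list means of -0.28 in Th1 and 0.14 in Th17 cells and a difference of 0.42. The rise in Th17 cells rested on 1 array: in 1 of the 8 fits that left out an array, the one without Th17 Tet2-deficient replicate 2, the Th17 mean was -0.08 and had the sign of Th1 cells (adjusted p = 0.0276 for the list, downward), and the list also turned downward in both fits that allowed for the sex-linked transcripts (0.432 and 0.0179). The difference between cell types turned sign in 0 of the 8 fits (0.20 to 0.64), so its direction did not rest on 1 array. Its size did depend on 1 array. Without Th17 Tet2-deficient replicate 2 the difference was 0.20, little more than the gap of 0.183 between wild-type Th1 replicates. Variation of cell cycle transcripts between cultures of 1 group is a candidate explanation, since the gap between the Tet2-deficient Th17 replicates was 0.445, more than either genotype difference, although the gaps in the other groups were 0.183 (wild-type Th1), 0.0832 (Tet2-deficient Th1) and 0.0216 (wild-type Th17). A different effect of Tet2 loss on proliferation in the 2 cell types, which the design names, also stays open.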

How the results depend on the processing

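The fits with the Y-linked level as a covariate, without the 2 single-sex Th17 arrays (wild-type replicate 1 and Tet2-deficient replicate 2) and with crossed replicate numbers were chosen after seeing the data. For named genes, 1984 values in the alternatives kept direction and side of the threshold, 15 lost the threshold, 7 gained it and 26 turned sign; for lists, 494 kept both, 160 lost the threshold and 6 turned. The cause was not tested unless given. Genes called in Th1 cells numbered 1, but 0 with no moderation (which leaves 4 residual degrees of freedom), only the groups compared, all probesets or the single-sex Th17 arrays left out, 34 at an unadjusted p under 0.01 and 1.5-fold, and 0 to 2 without 1 array. In Th17 cells 0 became 2 with array weights, 2 at an adjusted p under 0.1, 37 at the unadjusted threshold and 0 to 9 without 1 array. For the difference 0 became 127 at the unadjusted threshold and 0 to 4 without 1 array, and for the mean 2 with dim genes left out, 9 at the unadjusted threshold and 0 to 5 without 1 array.

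Between wild-type cell types, 1689 became 87 with no moderation, 622 with all probesets, 808 with the single-sex Th17 arrays left out, 2783 at an adjusted p under 0.1, 924 with 1.5-fold added, 964 at the unadjusted threshold and 667 to 1560 without 1 array. Between Tet2-deficient cell types, 2078 became 166, 1064 and 975 in the first 3 of these, 1187 with 1.5-fold added, 1209 at the unadjusted threshold and 815 to 2383 without 1 array. The correlation of the genotype effects ran from -0.0390 to 0.124 without 1 array, with -0.00541 without Th17 Tet2-deficient replicate 1.

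Camera with an estimated correlation called 0 lists in each of the 5 contrasts, and fry 0 for Th1, Th17, difference and mean. Without 1 array the counts were 3 to 8 (Th1, 7 with all arrays), 6 to 11 (Th17, 9), 5 to 13 (difference, 10), 2 to 8 (mean, 4) and 13 to 16 (wild-type cell types, 14). The mean count was 8 with the Y-linked level as a covariate and 7 with the single-sex Th17 arrays left out, and the cell type count 9 with dim genes left out. The cell cycle list turned downward in Th17 cells with the Y-linked covariate (adjusted p = 0.432) and the single-sex arrays left out (0.0179). Without 1 array the adjusted p ran from 1.56e-15 to 0.0828 for it, from 0.000255 to 0.960 for T cell receptor activation in Th17 cells and from 3.84e-11 to 0.445 for cell cycle on the mean.

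Log2 differences turned sign in Th1 cells for Il17f with quantile normalization (-0.0045) or median centring (-0.00041) and for Il10 with quantile normalization (0.0026), and in Th17 cells for Il17f with the Y-linked covariate (0.045). Without 1 array the Th1 differences were -0.11 to 0.035 for Tet2, -0.13 to 0.18 for Il17a, -0.15 to 0.15 for Il17f, -0.091 to -0.016 for Il10, -0.16 to 0.31 for Il2, -0.053 to 0.16 for Il4, -0.63 to 0.043 for Csf2 and -0.34 to 0.093 for Tnf. The Th17 differences were -0.045 to 0.017 for Ifng, -0.28 to 0.11 for Il17f, -0.093 to 0.062 for Il4, -0.14 to 0.13 for Foxp3, -0.087 to 0.0024 for Tet1 and -0.014 to 0.094 for Tet3.

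The labels share only a replicate number between groups, 2 per group. With that number as a replicate block, 1, 0, 0 and 0 genes were called for Th1, Th17, difference and mean, 1411 and 1810 between cell types, and 6, 8, 9, 4 and 15 lists. The block ended the calls of stress genes in Th1 cells (adjusted p = 0.0600), T cell receptor activation in Th17 cells (0.0739) and T cell cytokines for the difference (0.0741). Replicate differences of the groups correlated at -0.189 to 0.0534, and no pairing by equal numbers was seen in them. The lowest value was that of wild-type Th1 with wild-type Th17 cells, the sign that crossed numbers would give. Crossed numbers gave 1841 genes between wild-type cell types, against 1411 with equal numbers and 1689 with no block. Crossing was tried after that negative value was seen, so a gain over equal numbers follows from the choice. The counts thus neither show nor exclude a crossed pairing.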

Other observations

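The test for cells of both sexes, the Y-linked covariate on genes changed at least 1.5-fold and the comparison with Gm1966 were chosen after the values were seen. Transcription factors that set T helper lineages differed between wild-type Th17 and Th1 cells in both directions. Higher in Th17 cells were Rora, an orphan nuclear receptor of Th17 cells, at 2.13 (SE 0.135), Ikzf3 at 1.68, Ahr, the aryl hydrocarbon receptor, at 1.66 and Bcl6 at 1.18. Lower were Irf8 at -1.99, Prdm1 at -1.64, Eomes at -1.31 and Runx3, which acts with Tbx21 in Th1 cells, at -0.87. In all, 8 of 25 were called higher and 5 lower, both over all genes and adjusted over the list alone (camera adjusted p = 0.226 for the list). Inhibitory receptors also split: Ctla4 was higher in Th17 cells (1.26), and Lag3 (-1.20), Havcr2 (-1.05) and Tigit (-1.01) were lower, with 3 of 12 called higher and 4 lower both over all genes and adjusted over the list alone (camera adjusted p = 0.226).

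Among genes of the DNA methylation machinery, Tet1 (0.51) and Tet2 (0.44) were higher in wild-type Th17 than in Th1 cells, with 0.78 and 0.048 for the other Tet1 probesets, and Gadd45g (-1.06) and Gadd45b (-0.69), named for growth arrest and DNA damage, lower (camera adjusted p = 0.766 for 24 members). The p53 targets Sesn1 (1.25) and Trp53inp1 (1.01) and the survival factor Bcl2 (0.88) were higher in Th17 cells (camera adjusted p = 0.0918 for the list). Of 14 follicular helper genes, 4 were called higher and 2 lower over all genes, and 6 and 3 adjusted over the list alone, with Slamf6 (1.12), P2rx7 (1.07) and Icos (0.90) higher and Cd200 (-0.75) and Pdcd1 (-0.65) lower (camera adjusted p = 0.0619 for the list). With Tet2 loss, 16 genes near Tet2 on chromosome 3 were not called as a list in Th1 (adjusted p = 0.315) or Th17 cells (0.957), nor were 20 germline genes, which DNA methylation keeps silent (0.832 and 0.615).

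For the mean effect of Tet2 loss, the real grouping gave 0 called genes, so all 34 splits of the 8 arrays into 4 and 4 gave at least as many by construction (highest other 1) and that count says nothing about chance. At an unadjusted p under 0.05, 11 of 34 splits, the real one included, gave as many (1048 genes in the model with cell type and genotype terms, highest other 1765), so chance cannot be excluded for that count.

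The Th17 arrays differed in Xist and Y-linked transcripts, and cells of both sexes in 1 culture are a candidate explanation for 2 arrays, wild-type replicate 2 and Tet2-deficient replicate 1, which had both kinds well above the single-sex level. A linear dependence on the Y-linked level did not account for most of the size of the Th17 differences of 1.5-fold or more. Over the 47 such genes, sex-linked ones left out, the difference was taken with and without the Y-linked level as a covariate. The ratio of the first to the second had a median of 0.922 (quartiles 0.776 and 1.06). The median was 0.979 over the 16 named genes, which were picked for small p and so decide less. The slope on the covariate rests mostly on the Tet2-deficient Th17 arrays, with Y-linked means of 8.71 and 4.85. Xist did not follow that level closely: it read 5.20 in wild-type and 8.62 in Tet2-deficient replicate 1, at Y-linked means of 8.80 and 8.71. Wild-type Th17 replicate 2, with Xist at 10.1, had a Y-linked mean of 7.82. Tet2-deficient Th1 replicate 1, with Xist at 5.01, had 7.94. An effect of female cells that does not follow the Y-linked level is not removed. The adjustment therefore cannot decide whether sex composition was the whole cause of these differences. For the cell cycle list, which turned downward with the same covariate (adjusted p = 0.432), sex composition stays open. The sex of the mice is not given in the sources used here, so sex composition stays open for the other differences too, those between cell types included.

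Trim12a, a gene of the tripartite motif family, differed between replicates by -2.01 (wild-type Th1), 1.29 (Tet2-deficient Th1), 1.93 (wild-type Th17) and 0.91 (Tet2-deficient Th17), and Trim30d followed in 4 of 4 groups (-2.47, 0.59, 0.92 and 0.70). A genetic variant carried by some of the mice may explain this, but the test leaves it open: the 50 genes that varied most within groups held 9 neighbouring pairs of different families, against a mean of 4.94 in 10000 matched random sets, of which a share of 0.0743 held as many. Of these pairs 7 lie near Trim12a and 2 elsewhere, and a variant at 1 locus needs pairs only there. Probes shared between related Trim genes stay open too: Gm1966, which lies outside the rule for naming genes and was chosen after its values were seen, had the sign of Trim12a in 3 of 4 groups (-0.95, 0.86, 0.33 and -0.24). No biological explanation was tested.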
